A study of Mus musculus with 20 samples.

How the data were processed

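The series measured transcript levels in mouse cerebral cortex on 20 Agilent arrays with 22575 probes, each array carrying cocaine-exposed RNA in channel 1 and saline control RNA in channel 2. Per the labels' protocols, pregnant Swiss Webster dams received 20 mg/kg cocaine or saline under the skin 2 times daily from embryonic day 8 to embryonic day 18, and control dams were pair-fed. Fetal tissue was taken 1 h after the last injection with 2 fetuses per channel, adult tissue came from offspring on postnatal day 30, and 5 µg of RNA per channel was labelled with Genesphere 3DNA dendrimer reagents. Each slide within a region used its own control and experimental litters, per the labels, so the 5 arrays of a group were treated as separate biological samples. For 2 fetal occipital arrays that share a title number this is less sure. The labels do not say whether frontal and occipital tissue came from the same animals. The arrays fall into 4 groups of 5, namely fetal frontal, fetal occipital, adult frontal and adult occipital cortex.

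The deposited values are log2 ratios per probe, 1 column per array. The scanner, the image software and the normalization steps are not given in the sources used here, and neither intensities nor background were analysed here, so signal over background is unknown for every value and only the number of arrays limits the stated precision. The direction cocaine over saline is likely and not stated: the labels put cocaine in channel 1 and saline in channel 2 on all arrays, each with its own Alexa dye. The lowest correlation of a pair of arrays over all probes was -0.044. Such correlations cannot show the direction, since they stay the same when all ratios are turned in sign. Because no dye swap is labelled, a fixed difference between the dyes for a probe remains in every group mean. Channel 1 of fetal frontal replicate 1 lists both dyes, and 2 fetal occipital arrays share the title number 1 and are called replicates 1 and 1b. Array medians of the deposited values lay between -0.26 and 0.32, and each array carried from 6 to 27 values equal to its maximum, between 15.51 and 17.37, which were treated as missing markers. Exact 0 values, 1368 among 451500, were kept.

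From there each array was centred on its median, and probes with at least 3 values in every group were kept, which left 22567 and removed 8. One limma model (limma 3.58.1 in R 4.3.3) of the 4 group means was fitted to all 20 arrays with moderated variances. All contrasts were two-sided with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. They were the 4 group means against 0, the mean of both regions at each age against 0, occipital minus frontal at each age, and adult minus fetal. Probes were named from the platform annotation, in which 18218 probes have 1 gene symbol, 16 have several and 4341 have none; symbols were checked by gene identifier against a RefSeq gene table (GRCm38.p6), which changed 0 of them. Probes were not averaged per gene, and a gene counted as disagreeing where its probes passed in opposite directions.

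Genes were named by a rule fixed before the data were examined, as were the comparisons, the gene lists and the first set of alternative settings. It took, in each cocaine over saline comparison, the 10 highest and the 10 lowest probes with 1 symbol that passed and had the same sign on every array of the comparison. For the region and age differences it took the 5 largest in each direction that passed, or the 3 with the smallest p where none did, and from each list described up to 4 members with the smallest p. In all, 37 gene lists with 928 members, 826 of them measured, were fixed for cell death, stress, transmitter systems, housekeeping machinery, cell types of the cortex and neighbouring tissues. Lists were tested with camera at a preset correlation of 0.01, again with the correlation estimated from the data, and with fry, which asks whether a list's genes move one way on balance.

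That first set of alternative settings held no centring, scaling to equal spread, quantile normalization, stricter and looser filters, exact 0 as missing, fetal frontal replicate 1 turned in sign, array weights, robust regression, only the arrays of a comparison, a replicate block, averaging of a gene's probes, a threshold of 0.1 and leaving out each array. Alternatives chosen after seeing the data removed a brightness trend, a trend with position on the array, or both, from each array by loess (spans 0.3 and 0.05), or left out fetal occipital replicates 1 and 1b together. Since intensities were not at hand, a brightness score was built from the ratios: a dim spot is a quotient of small whole numbers, and the smallest pair of whole numbers up to 400 that gives a ratio within 0.001 on the log2 scale sets the score. Among 565 ratios of 82 spots that were at 0 or at the marker on at least 8 arrays, 95.9% came from whole numbers up to 20, against 12.7% of random ratios. In simulated arrays the score followed the true brightness with a Spearman correlation of 0.896 over 5000 spots, 0.967 over 2767 dim spots and 0.0861 over 1707 bright spots, so it does not rank bright spots. The simulated ratios were drawn around 0 afresh for each array, so the simulation cannot show whether the score picks up the ratio itself. Position was taken from the probe number with 215 spots per row, the lag at which the values repeat. The score and the figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

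The model was tested on simulated data over the 22567 probes, with 200 probes changed by log2 sizes of 0.5, 1, 1.5 or 2. For the fetal frontal mean it recovered 26% of the probes changed by 1 and 98% of those changed by 2, and for the adult mean of both regions 70% and 98%. It recovered 0% and 46% for the fetal region difference, and 20% and 90% for the age difference; from 2 to 7 unchanged probes were called in these 4 runs. A list shifted by 0.8 was called in all 4 runs, with 0 other lists. The simulated noise was independent between probes and held no dye, brightness or position trend. These runs therefore do not show how many false calls the real data give.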

Results

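Transcript ratios of cocaine-exposed over saline-exposed mouse cortex were measured in fetal frontal, fetal occipital, adult frontal and adult occipital cortex, with 5 arrays in each group. The frontal and occipital cerebral wall were studied apart because their dopaminergic innervation differs, and the treatment was chosen, per the labels, because it reduces cortical mass in the offspring. Values are log2 ratios of cocaine over saline relative to each array's median, given as mean ± SE of the limma model. Ratios of the 20 arrays correlated across probes with Pearson coefficients from -0.04 to 0.86 and a median of 0.51, where probes are not independent replicates. The spread of ratios within an array, as the median absolute deviation, ran from 0.49 in fetal frontal replicate 3 to 1.18 in adult frontal replicate 3.

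A set of genes had large ratios in several groups. Mtcl1, a microtubule-linking protein, stood at 3.64 ± 0.51 in fetal occipital, 3.37 ± 0.51 in adult frontal and 3.25 ± 0.51 in adult occipital cortex on 5 of 5 arrays each. Rgs20, a regulator of G protein signalling, stood at 3.61 ± 0.44 in fetal frontal and 3.16 ± 0.44 in adult occipital cortex. In all 4 groups 1092 probes were higher and 1191 lower. The fetal frontal mean ratios correlated with those of adult frontal cortex at 0.82 and with those of fetal occipital cortex at 0.65 across probes. The 2 adult regions correlated at 0.92, and the weakest pair, fetal occipital and adult frontal cortex, at 0.50. Between the adult regions 4644 probes were higher in both, 4916 lower in both and 1 opposite, where independent calls would give 1457 and 1596. Opposite calls numbered 259 between fetal occipital and adult frontal cortex and 123 between fetal and adult occipital cortex.

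**Figure D1:**
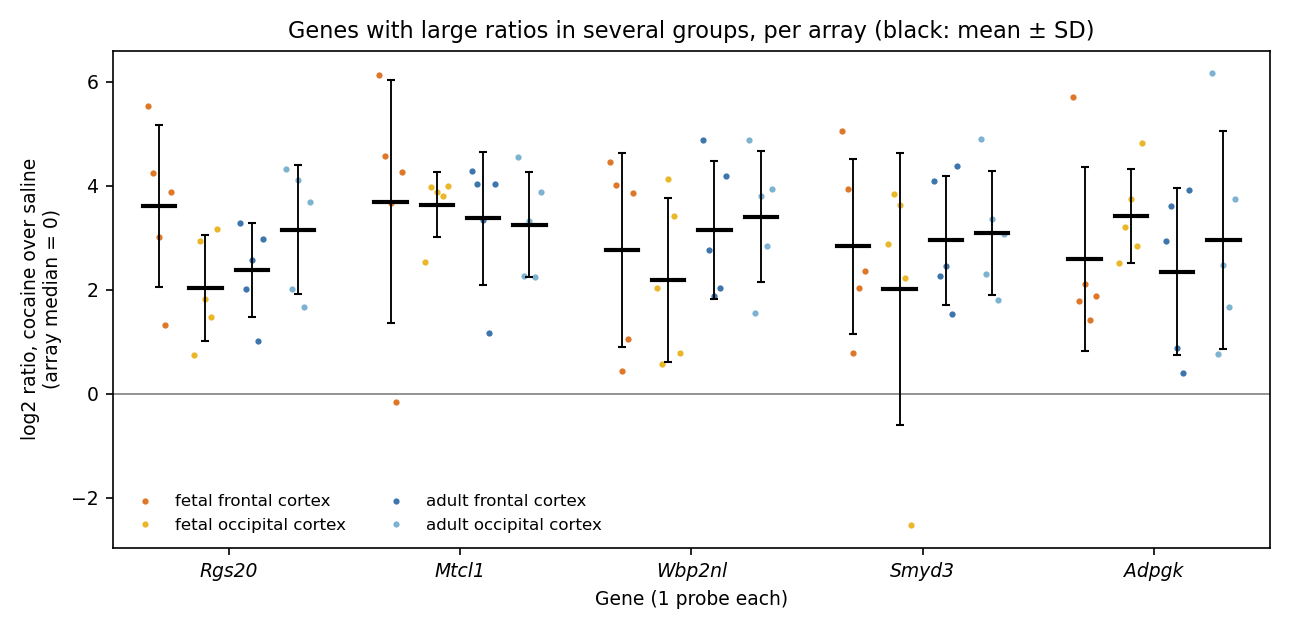
Log2 ratio of cocaine over saline (vertical axis, array median at 0) for 5 genes on each of the 20 arrays, with points for arrays, colours for the 4 groups and black bars for mean ± SD of 5 arrays. Rgs20 lies above 0 on all 20 arrays and Smyd3 has a fetal occipital mean of 2.01 with 1 array below 0.

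Ratios also followed the brightness score of a probe. The Spearman correlation of log ratio with the brightness score was positive on 20 of 20 arrays, from 0.0903 in fetal occipital replicate 1 to 0.680 in adult frontal replicate 3. In the 10% of probes with the lowest score the median ratio was -0.99 in fetal frontal, -0.64 in fetal occipital, -1.53 in adult frontal and -1.16 in adult occipital cortex, against 1.00, 0.52, 1.27 and 1.02 in the 10% with the highest score. Olfactory receptors, odorant receptors of the nose that cortex hardly expresses, served as a measure of probes near background. Their 803 probes had medians of -0.36, -0.15, -0.66 and -0.38 in the same order of groups. The 119 vomeronasal receptor probes had -0.61, -0.27, -0.98 and -0.61. These medians stayed below 0 without centring, with scaling and with quantile normalization. With the brightness trend removed they shrank, in the same order, to -0.23, -0.09, -0.38 and -0.21 for olfactory probes. For vomeronasal probes they shrank to -0.20, -0.14, -0.47 and -0.23. Receptor probes also went both ways, as 113 olfactory probes passed higher and 383 lower in adult frontal cortex.

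**Figure D2:**
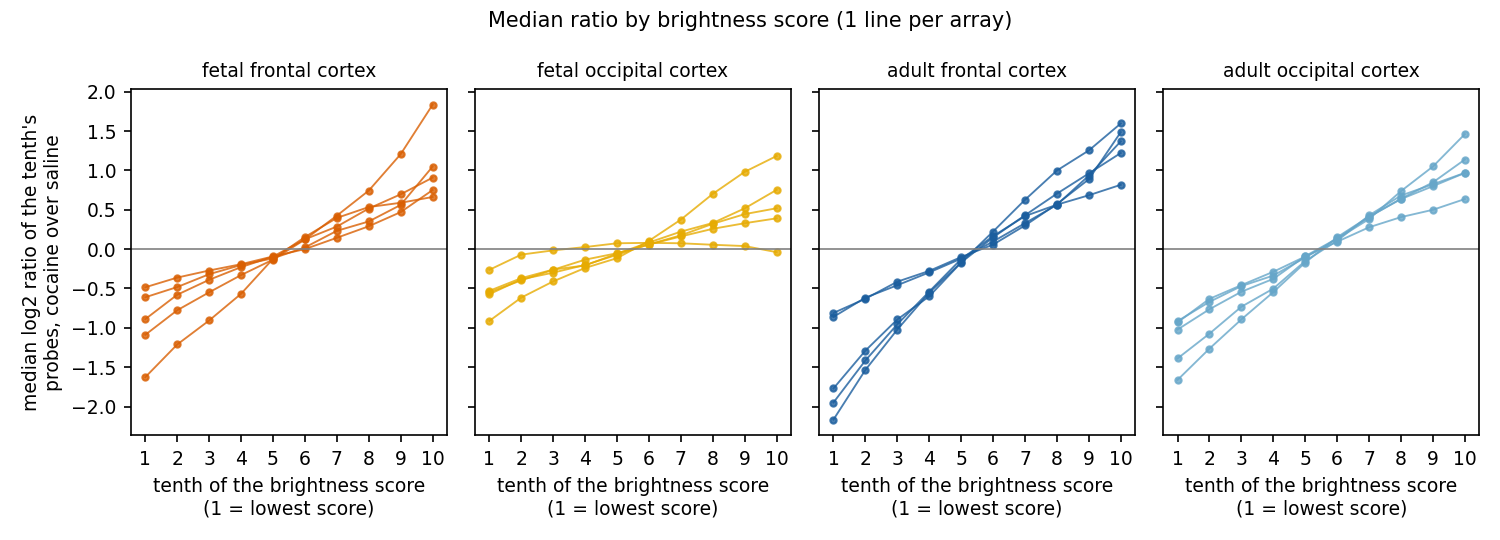
Median log2 ratio of cocaine over saline (vertical axis) in each 10% of the probes by brightness score (horizontal axis, lowest score first), 1 panel per group and 1 line per array. The group medians run from -1.53 to 1.27 in adult frontal cortex and from -0.64 to 0.52 in fetal occipital cortex, where replicate 1 is nearly flat.

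The fetal frontal comparison asked which transcripts differed after exposure in the frontal cerebral wall. Mtcl1 averaged 3.70 ± 0.51 with 1 of 5 arrays below 0. Among genes with the same sign on every array those with the largest rise besides Rgs20 were Smyd3, a histone methyltransferase (2.83 ± 0.61), Wbp2nl (2.77 ± 0.53), Gse1 (2.68 ± 0.40), Ten1, a telomere-capping protein (2.64 ± 0.38), and Adpgk, an ADP-dependent glucokinase (2.58 ± 0.57). Then came Usp4, a deubiquitinase (2.50 ± 0.36), the anticoagulant protein S gene Pros1 (2.48 ± 0.42), Lmbrd2 (2.47 ± 0.53) and Dusp11 (2.39 ± 0.37). The largest falls were of Vmn2r37, a vomeronasal receptor (-2.69 ± 0.37), the phosphate transporter Slc34a2 (-2.53 ± 0.47), the taste-cell channel Trpm5 (-2.49 ± 0.37) and G3bp1 (-2.44 ± 0.53), followed by the proton pump subunit Atp6v1g3 (-2.44 ± 0.51), the hair keratin-associated Krtap15 (-2.27 ± 0.38), Trdn (-2.23 ± 0.40), Rfpl4 (-2.18 ± 0.34), Elf3 (-2.17 ± 0.50) and Slco1a6 (-2.15 ± 0.42). All 20 had the same sign on 5 of 5 arrays, with limma adjusted p from 6.85e-05 to 0.00164. Over all probes 8359 of 22567 passed, 4217 higher and 4142 lower. A second G3bp1 probe gave 0.75 ± 0.33 and did not pass, and 66 genes had probes that passed in opposite directions.

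Genes of protein synthesis rose together in fetal frontal cortex. Of 52 measured ribosomal protein genes 46 rose, 1 fell and 5 did not pass, with 47 and 1 when adjusted over the list alone, and the median was 1.08. Rpl28 stood at 1.59 ± 0.30 and Rps19 at 1.60 ± 0.31. Their camera adjusted p was 9.21e-12, but adjusted p = 0.791 with an estimated correlation, and their probes lay at percentile 87.0 of the brightness score. Respiratory chain genes followed, with 23 of 57 higher, 0 lower and 34 not passing (23 and 1 adjusted over the list alone), Uqcrb at 1.65 ± 0.31 and Ndufa10 at 1.70 ± 0.34. Their camera adjusted p was 3.94e-06, with adjusted p = 0.794 with an estimated correlation, at a brightness percentile of 82.8. Among markers of intermediate progenitors and newborn neurons 7 of 16 rose, 0 fell and 9 did not pass (8 and 0 adjusted over the list alone). The neuronal transcription factors among them were Sox4 (1.85 ± 0.46), Sox11 (1.37 ± 0.27 and 1.24 ± 0.31 at 2 probes) and Neurog1 (0.95 ± 0.25). With the brightness trend removed 1 of the 2 Sox11 probes stood at -0.15. With fetal frontal replicate 1 turned in sign Sox4 stood at -0.23. The newborn neuron list had a brightness percentile of 60.9, a camera adjusted p of 0.00128 and an adjusted p = 0.101 with an estimated correlation. Heat shock and unfolded protein genes had 13 of 26 higher, 2 lower and 11 not passing (16 and 3 adjusted over the list alone), with the stress factor Ddit3 at 1.60 ± 0.27 and the chaperones Hspa9 at 1.68 ± 0.30 and Hspa8 at 1.58 ± 0.32. Oxidative stress genes had 11 of 25 higher, 2 lower and 12 not passing (11 and 2 adjusted over the list alone), with the glutathione transferase Gsta1 at 1.79 ± 0.31 and the ferritin Ftl1 at 1.89 ± 0.35. Both had a camera adjusted p of 0.00451 and an adjusted p = 0.791 with an estimated correlation, at brightness percentiles of 73.0 and 72.1. Medians after removal of the brightness trend went from 1.08 to 0.28 for ribosomal, from 0.65 to 0.23 for respiratory chain, from 0.77 to 0.67 for newborn neuron, from 0.82 to 0.40 for heat shock and from 0.56 to 0.25 for oxidative stress genes. Ribosomal and newborn neuron genes kept their camera call, with adjusted p of 0.0181 and 0.0141.

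Genes of cell death, dopamine and rapid neuronal response went both ways in fetal frontal cortex. Over all probes 37.0% passed in this group, the share to set beside these counts. Of 31 pro-apoptotic genes 5 rose, 5 fell and 21 did not pass (5 and 4 adjusted over the list alone), among them the mitochondrial protease Htra2 (1.69 ± 0.33) and the p53 relative Trp73 (-1.73 ± 0.33). Of 21 survival genes 5 rose, 3 fell and 13 did not pass (6 and 3 adjusted over the list alone), with Bcl2 at 1.24 ± 0.29, Birc5 at 1.39 ± 0.29 and Cflar at -1.17 ± 0.29. Of 26 immediate early genes 4 rose, 3 fell and 19 did not pass, also 4 and 3 adjusted over the list alone, with Nr4a2 at 1.23 ± 0.30, Fosb at -0.99 ± 0.28 and Npas4 at -1.57 ± 0.31. Of 17 dopamine system genes 3 rose, 4 fell and 10 did not pass, also 3 and 4 adjusted over the list alone, including the receptor Drd3 (1.66 ± 0.30), the vesicular transporter Slc18a2 (1.37 ± 0.30), the cofactor enzyme Gch1 (-1.19 ± 0.26) and the oxidase Maob (-1.35 ± 0.31). None of these 4 lists passed camera, with adjusted p from 0.601 to 0.987. The pro-apoptotic and immediate early lists had a median below 0 beside an upward test direction. With fetal frontal replicate 1 turned in sign 9 probes passed, and without replicate 2 the count was 5243. As deposited, replicate 1 correlated across probes with the other arrays of its group from 0.36 to 0.57. Turning its sign therefore sets it against them. With the brightness trend removed the count was 3424, of which 2470 were among the 8359 in the same direction, and with the position trend removed as well Birc5, Drd3 and Slc18a2 stood at -0.026, -0.17 and -0.045.

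The fetal occipital comparison asked the same of the cerebral wall behind the level of the hippocampus. Among genes with the same sign on every array the largest rises were of Mtcl1, Adpgk (3.43 ± 0.57), the zinc transporter Slc30a9 (2.76 ± 0.54), Wbp2nl (2.19 ± 0.53) and the DNA topoisomerase Top2b (2.12 ± 0.30). They were followed by the cytokine Il24 (2.04 ± 0.31), Rgs20 (2.03 ± 0.44), 4933402J07Rik (1.99 ± 0.30), the mitochondrial ribosomal gene Mrpl1 (1.96 ± 0.39) and the ciliary transport gene Ift81 (1.92 ± 0.41). The collagen gene Col1a2 fell by 3.11 ± 0.38, the chemokine Ccl8 by 2.86 ± 0.44 and Tmcc3 by 2.76 ± 0.53. Next were the olfactory receptors Olfr1301 (-2.68 ± 0.42), Olfr862 (-2.67 ± 0.35) and Olfr1355 (-2.64 ± 0.46), the vomeronasal receptor Vmn1r219 (-2.68 ± 0.35), Cd300lg (-2.63 ± 0.37), Slc10a6 (-2.59 ± 0.32) and the forebrain homeobox gene Lhx8 (-2.58 ± 0.31). All 20 had the same sign on 5 of 5 arrays, with limma adjusted p from 1.4e-05 to 0.00446. A total of 5576 probes passed, 2380 higher and 3196 lower. Second probes gave 0.55 ± 0.35 for Mtcl1, which did not pass, and -0.90 ± 0.28 for Tmcc3. By probe number and the inferred row length, the named falls except that of Col1a2 lay towards the same end of the array rows. The named rises were spread along the rows. Position explained from 19.4% (replicate 3) to 45.9% (replicate 1b) of the variance of these arrays. Position on the array therefore stays open as a source of those falls.

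Ribosomal protein genes were the one list called in fetal occipital cortex, with 17 of 52 higher, 2 lower and 33 not passing (19 and 2 adjusted over the list alone) and a median of 0.56. Rpl34 stood at 1.83 ± 0.32 and Rplp0 at 1.53 ± 0.33. The camera adjusted p was 0.000611, with adjusted p = 0.947 with an estimated correlation and a fry adjusted p of 0.127, at the same brightness percentile of 87.0. The median was 0.09 and the camera adjusted p 0.996 with the brightness trend removed. Pro-apoptotic genes numbered 4 higher, 5 lower and 22 not passing, also 4 and 5 adjusted over the list alone, with the caspase activator cytochrome c gene Cycs at 0.94 ± 0.24 and Cideb at -1.32 ± 0.33. Survival genes numbered 3 higher, 3 lower and 15 not passing, also 3 and 3 adjusted over the list alone, with Akt2 at 1.24 ± 0.29 and Pdpk1 at -1.66 ± 0.43. Immediate early genes numbered 2 higher, 3 lower and 21 not passing, also 2 and 3 adjusted over the list alone, with Jun at 0.88 ± 0.26 and Dusp6 at -1.09 ± 0.26. In the dopamine system 2 rose, 5 fell and 10 did not pass, also 2 and 5 adjusted over the list alone, the falls including the striatal phosphoprotein Ppp1r1b (-1.67 ± 0.45), the synthesis enzyme Ddc (-1.59 ± 0.46) and the G protein Gnal (-1.72 ± 0.50). These 4 lists had camera adjusted p from 0.943 to 0.951, and over all probes 24.7% passed in this group. The test pointed up for pro-apoptotic and immediate early genes, whose medians were -0.05 and -0.02, and down for the dopamine system, whose median was 0.05. Fitted on its own arrays the comparison gave 1744 probes. Without replicates 1 and 1b together it gave 3646, without replicate 5 alone 3109 and without replicate 1b alone 3477. With the position trend removed the count was 3089, and with both trends removed Slc18a2 moved from 1.01 ± 0.30 to -0.020 and Xiap from -1.04 ± 0.32 to 0.26.

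The mean of both fetal regions combined 10 arrays. Among genes with the same sign on all of them, which leaves out Mtcl1 (3.67 ± 0.36), Adpgk (3.01 ± 0.40), Rgs20 (2.82 ± 0.31), Wbp2nl (2.48 ± 0.38) and Top2b (2.23 ± 0.21) rose most. Next were Pros1 (2.13 ± 0.30), Ift81 (2.12 ± 0.29), Ten1 (2.11 ± 0.27), Il24, the RNA helicase Dhx57 (1.96 ± 0.22) and Olfr1132 (1.94 ± 0.24). Krtap15 (-2.41 ± 0.27), G3bp1 (-2.40 ± 0.37), Slc34a2 (-2.27 ± 0.33), Olfr1301 (-2.18 ± 0.30) and the endocytic adaptor Ston2 (-2.16 ± 0.29) fell most, ahead of Trpm5 (-2.15 ± 0.26), Ctag2 (-2.11 ± 0.25), Glis1 (-2.10 ± 0.32), Dhrs7c (-2.05 ± 0.22) and the cytokinesis gene Ect2 (-2.04 ± 0.22). All 20 had the same sign on 10 of 10 arrays, with limma adjusted p from 1.97e-07 to 1.52e-05. By probe number, the named falls lay towards the same end of the array rows as those in fetal occipital cortex. Position on the array stays open as their source too. Over all probes 11105 passed, 5297 higher and 5808 lower. The count was 6826 with fetal frontal replicate 1 turned in sign and 6878 with the brightness trend removed. Ribosomal protein genes had 38 higher, 1 lower and 13 not passing, respiratory chain genes 26, 2 and 29, heat shock genes 15, 4 and 7, and newborn neuron genes 7, 0 and 9, the same higher and lower counts as adjusted over the list alone. Oxidative stress genes had 9 higher, 3 lower, 12 not passing and 1 with disagreeing probes, also 9 and 3 adjusted over the list alone. The camera adjusted p of these 5 lists ran from 2.93e-09 to 0.0116, with adjusted p = 0.399 with an estimated correlation for newborn neurons and 0.909 for the others. With the brightness trend removed 0 of these 5 lists kept their call. Olfactory receptor probes had a median of -0.29.

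In adult frontal cortex, taken on postnatal day 30 after exposure had ended before birth, the question was which differences were present in the offspring. Among genes with the same sign on every array Mtcl1 rose most, followed by Wbp2nl (3.15 ± 0.53), Smyd3 (2.95 ± 0.61), Lmbrd2 (2.67 ± 0.53), Wdr37 (2.56 ± 0.41) and Pros1 (2.49 ± 0.42). Next were the ubiquitin-conjugating enzyme Ube2s (2.48 ± 0.34), the sperm protamine Prm1 (2.47 ± 0.38), the vitamin transporter Slc5a6 (2.44 ± 0.38) and the mitochondrial glutamate carrier Slc25a22 (2.42 ± 0.32). The largest falls were of the interferon-induced Trim30a (-3.16 ± 0.34), Uba1y (-3.10 ± 0.41), the kinetochore gene Spc24 (-3.07 ± 0.31), the death ligand Tnfsf10 (-3.06 ± 0.30) and the histone gene H3c1 (-2.94 ± 0.38). Next were Efhb (-2.92 ± 0.33), Rab26 (-2.87 ± 0.43), the GABA-degrading enzyme Abat (-2.85 ± 0.34), Oxgr1 (-2.80 ± 0.41) and Stx17 (-2.77 ± 0.39). All 20 had the same sign on 5 of 5 arrays, with limma adjusted p from 1.57e-07 to 0.000191. A total of 12664 probes passed, 6040 higher and 6624 lower, and 8294 passed with the brightness trend removed. Second probes gave 0.77 ± 0.34 for Mtcl1, -0.11 ± 0.32 for Wdr37, 0.33 ± 0.32 for Ube2s and 0.48 ± 0.28 for Uba1y, none of which passed. In adult frontal cortex 145 genes had probes that passed in opposite directions.

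Genes of energy, synapse and glia rose together in adult frontal cortex. Of 57 respiratory chain genes 45 rose, 0 fell and 12 did not pass (46 and 0 adjusted over the list alone), with Atp5k at 1.72 ± 0.29 and Cox8a at 1.74 ± 0.31. Ribosomal protein genes had 44 of 52 higher, 1 lower, 5 not passing and 2 with disagreeing probes (45 and 2 adjusted over the list alone), with Rps24 at 1.93 ± 0.29 and Rps2 at 1.92 ± 0.30. Of 30 synaptic genes 20 rose, 1 fell, 8 did not pass and 1 had disagreeing probes (21 and 1 adjusted over the list alone). The release proteins Snap25 (1.60 ± 0.30), Cplx2 (1.77 ± 0.30) and Syn1 (1.59 ± 0.31) rose while Syn3 fell by 2.10 ± 0.29. Of 15 astrocyte genes 10 rose, 0 fell and 5 did not pass, with the calcium-binding protein S100b at 1.68 ± 0.26 and Apoe at 1.68 ± 0.29. Of 20 myelin genes 10 rose, 1 fell and 9 did not pass, with Mobp at 1.99 ± 0.29, Olig1 at 1.69 ± 0.33 and Mbp at 1.83 ± 0.37. Both lists gave the same counts adjusted over the list alone. Heat shock genes had 15 of 26 higher, 2 lower and 9 not passing (15 and 3 adjusted over the list alone), with the stress sensor Atf6 at 1.90 ± 0.27 and Dnajb9 at 2.08 ± 0.33. Oxidative stress genes had 14 of 25 higher, 2 lower and 9 not passing, also 14 and 2 adjusted over the list alone, with Gpx4 at 1.68 ± 0.30 and Nqo1 at -1.61 ± 0.29. Camera adjusted p ran from 3.46e-10 to 0.0137 over these 7 lists, with adjusted p = 0.446 with an estimated correlation for oxidative stress and 0.392 for the others. Their brightness percentiles were 82.8 for respiratory chain, 87.0 for ribosomal, 64.2 for synaptic, 46.5 for astrocyte, 59.0 for myelin, 73.0 for heat shock and 72.1 for oxidative stress genes. After removal of the brightness trend the medians of these 7 lists lay between 0.24 for oxidative stress and 0.83 for synaptic genes, and all but the oxidative stress and myelin lists kept their camera call.

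Cell death, survival, immediate early and dopamine genes again included members in both directions in adult frontal cortex. Over all probes 56.1% passed in this group, the share to set beside these counts. Pro-apoptotic genes numbered 10 higher, 7 lower and 14 not passing, with Cidea at 1.66 ± 0.32, Pmaip1 at -1.81 ± 0.32 and Casp8 at -1.42 ± 0.28. Survival genes numbered 8 higher, 2 lower, 10 not passing and 1 with disagreeing probes, with Bcl2 at 1.69 ± 0.29 and Cflar at -1.69 ± 0.29. Immediate early genes numbered 8 higher, 5 lower, 12 not passing and 1 with disagreeing probes, with Dusp6 at 1.44 ± 0.26, Fosl2 at 1.75 ± 0.35 and Nr4a1 at 1.55 ± 0.31. In the dopamine system 5 rose, 4 fell and 8 did not pass, with the oxidase Maoa at 1.85 ± 0.32, Slc18a2 at 1.69 ± 0.30, the receptor Drd2 at -1.31 ± 0.27 and Maob at -1.49 ± 0.31. The higher and lower counts of these 4 lists were the same adjusted over the list alone, and their camera adjusted p ran from 0.231 to 0.639.

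Among genes with the same sign on every array, adult occipital cortex gave the largest rises for Wbp2nl (3.41 ± 0.53), Mtcl1, Rgs20, Smyd3 (3.09 ± 0.61), Slc30a9 (3.07 ± 0.54) and Adpgk (2.97 ± 0.57). Next were Usp4 (2.85 ± 0.36), Tti1 (2.74 ± 0.52), Slc5a6 (2.70 ± 0.38) and the stress peptide urocortin 3 gene Ucn3 (2.67 ± 0.43). The largest falls were of Zkscan1 (-2.43 ± 0.45), H3c1 (-2.38 ± 0.38), the phosphatase Ptpn13 (-2.29 ± 0.32), Clec4e (-2.21 ± 0.35), Olfr1008 (-2.16 ± 0.34), Triml1 (-2.15 ± 0.29), Olfr671 (-2.14 ± 0.30), Klk1b27 (-2.12 ± 0.42), the sodium leak channel Nalcn (-2.10 ± 0.34) and Cdcp3 (-2.10 ± 0.28). All 20 had the same sign on 5 of 5 arrays, with limma adjusted p from 3.81e-05 to 0.00053. Second probes gave 0.59 ± 0.35 for Mtcl1, -0.53 ± 0.33 for Zkscan1 and 0.40 ± 0.28 for Nalcn, none of which passed. A total of 10882 probes passed, 5444 higher and 5438 lower, and 5334 passed with the brightness trend removed.

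The lists called in adult occipital cortex were those of adult frontal cortex. Respiratory chain genes had 38 higher, 0 lower and 19 not passing (40 and 0 adjusted over the list alone), with Atp5k at 1.61 ± 0.29 and Ndufb5 at 1.80 ± 0.35. Ribosomal protein genes had 39 higher, 1 lower, 11 not passing and 1 with disagreeing probes (41 and 1 adjusted over the list alone), with Rps7 at 1.81 ± 0.29. Synaptic genes had 21 higher, 1 lower, 7 not passing and 1 with disagreeing probes, also 21 and 1 adjusted over the list alone, with Camk2a at 1.19 ± 0.30, the glutamate transporter Slc17a6 at 1.19 ± 0.25 and Syn3 at -1.64 ± 0.29. Astrocyte genes had 8 higher, 0 lower and 7 not passing, with S100b at 1.35 ± 0.26 and Gfap at 1.25 ± 0.28. Myelin genes had 9 higher, 0 lower and 11 not passing, with Mobp at 1.31 ± 0.29, Olig1 at 1.54 ± 0.33 and Cnp at 0.93 ± 0.28, a value of -0.042 with the brightness trend removed. Heat shock genes had 15 higher, 2 lower and 9 not passing, with Dnajb9 at 1.93 ± 0.33 and the inducible Hspa1a at -1.91 ± 0.37. Oxidative stress genes had 13 higher, 2 lower and 10 not passing, with Gsr at 1.22 ± 0.31 and Nqo1 at -1.43 ± 0.29. The higher and lower counts of the astrocyte, myelin, heat shock and oxidative stress lists were the same adjusted over the list alone. Camera adjusted p ran from 1.29e-09 to 0.0131 over these 7 lists, with adjusted p = 0.564 with an estimated correlation for respiratory chain, synaptic, astrocyte and myelin genes and 0.581 for the other 3. After removal of the brightness trend the medians lay between 0.24 for oxidative stress and 0.57 for heat shock genes, and the ribosomal, respiratory chain and synaptic lists kept their camera call. Olfactory receptor probes had a median of -0.38.

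Pro-apoptotic genes in adult occipital cortex numbered 6 higher, 7 lower and 18 not passing, with Cidea at 1.42 ± 0.32 and Casp8 at -1.36 ± 0.28, also 6 and 7 adjusted over the list alone. Survival genes numbered 6 higher, 2 lower and 13 not passing, with Bcl2 at 1.26 ± 0.29 and Xiap at -1.51 ± 0.32, also 6 and 2 adjusted over the list alone. Immediate early genes numbered 6 higher, 4 lower and 16 not passing (5 and 3 adjusted over the list alone), with Nr4a2 at 1.48 ± 0.30 and Npas4 at -1.05 ± 0.31. In the dopamine system 5 rose, 2 fell and 10 did not pass, also 5 and 2 adjusted over the list alone, with Maoa at 1.80 ± 0.32, Gch1 at -1.29 ± 0.26 and the striatal regulator Rgs9 at 1.08 ± 0.31. Camera adjusted p for these lists ran from 0.477 to 0.889, and over all probes 48.2% passed in this group.

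The mean of both adult regions gave 14975 probes past the threshold in limma, 7375 higher and 7600 lower. Among genes with the same sign on all 10 arrays Mtcl1 (3.31 ± 0.36), Wbp2nl (3.28 ± 0.38), Smyd3 (3.02 ± 0.43), Rgs20 (2.77 ± 0.31) and Slc30a9 (2.70 ± 0.38) rose most, ahead of Adpgk (2.66 ± 0.40), Lmbrd2 (2.60 ± 0.37), Slc5a6 (2.57 ± 0.27), Usp4 (2.52 ± 0.26) and Wdr37 (2.45 ± 0.29). H3c1 (-2.66 ± 0.27), Trim30a (-2.54 ± 0.24), Spc24 (-2.42 ± 0.22), Nalcn (-2.40 ± 0.24) and the meiosis gene Stra8 (-2.40 ± 0.22) fell most, followed by Card6 (-2.38 ± 0.24), Uba1y (-2.37 ± 0.29), Abat (-2.36 ± 0.24), the autophagy gene Epg5 (-2.36 ± 0.24) and Triml1 (-2.35 ± 0.20). All 20 had the same sign on 10 of 10 arrays. The second probes of Nalcn and Uba1y passed in the opposite direction, at 0.52 ± 0.20 and 0.54 ± 0.20. Respiratory chain genes had 50 higher, 0 lower and 7 not passing (51 and 0 adjusted over the list alone), ribosomal genes 44, 1 and 5 with 2 disagreeing (45 and 1), and synaptic genes 24, 1 and 4 with 1 disagreeing, also 24 and 1 adjusted over the list alone. Astrocyte genes had 11, 0 and 4, myelin genes 12, 1 and 7, heat shock genes 18, 3 and 5, and oxidative stress genes 15, 1 and 8 with 1 disagreeing, with the same higher and lower counts adjusted over the list alone. The camera adjusted p of these 7 lists ran from 2.42e-10 to 0.0105, with adjusted p = 0.43 with an estimated correlation for each. With the brightness trend removed 5 of these 7 lists kept their call. Olfactory receptor probes had a median of -0.53.

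**Figure D3:**
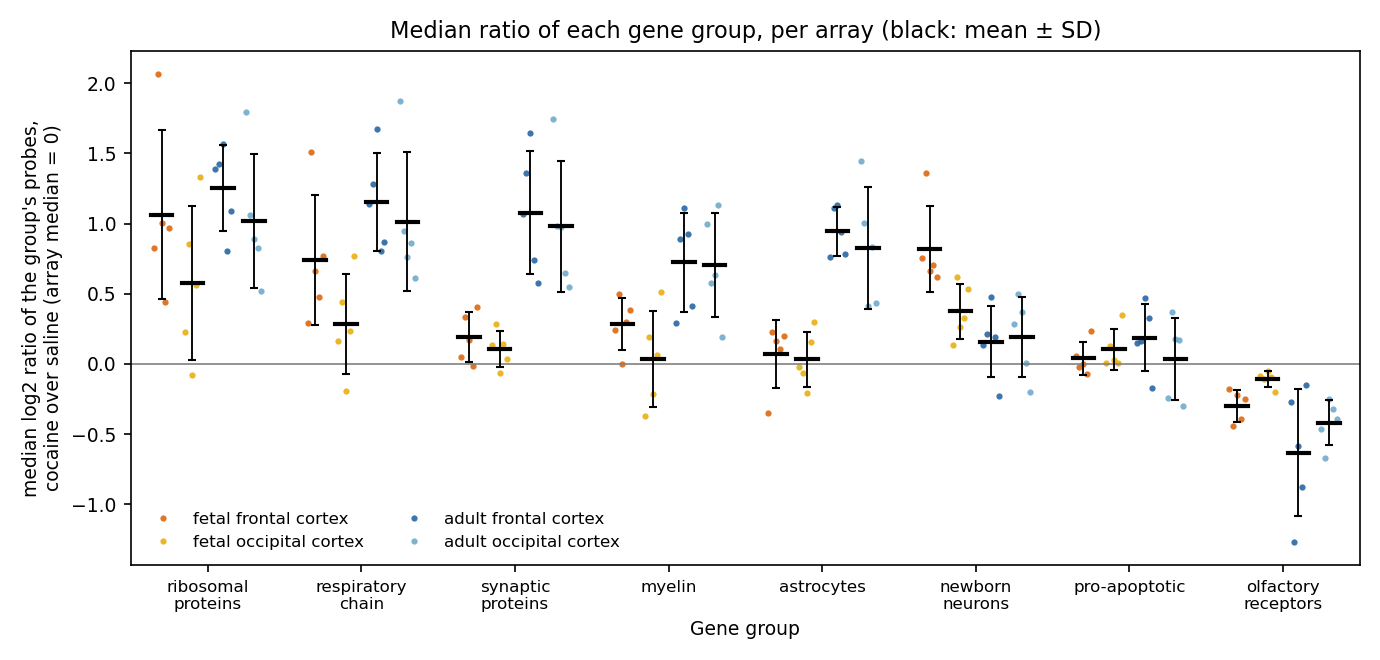
Median log2 ratio of cocaine over saline (vertical axis, array median at 0) of the probes of 8 gene groups on each array, with points for arrays, colours for the 4 groups of 5 arrays and black bars for mean ± SD. Respiratory chain, synaptic, astrocyte and myelin medians lie above 0 on all adult arrays, and olfactory receptor medians lie below 0 on all 20 arrays.

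The region comparison asked whether the response differed between frontal and occipital cortex. In the fetus 5 probes had a lower ratio in occipital than in frontal cortex and 0 a higher one. They were the signalling adaptor Dapp1 (difference -2.69 ± 0.50), the platelet glycoprotein Gp1bb (-2.65 ± 0.50), the plasminogen-binding Clec3b (-2.37 ± 0.44), Pdlim4 (-2.17 ± 0.40) and a probe without a gene name (-2.92 ± 0.55), each with a limma adjusted p of 0.0446 over 10 arrays. Dapp1 averaged 1.24 in frontal and -1.45 in occipital arrays. At an unadjusted p under 0.05 there were 3504 probes. The smallest p among higher ratios belonged to Slc10a3 (1.75 ± 0.37), Vwa8 (1.85 ± 0.40) and Tceanc (1.99 ± 0.46), with limma adjusted p from 0.0686 to 0.0848, and a second Vwa8 probe gave 0.46 ± 0.43. Ribosomal (median difference -0.55), respiratory chain (-0.35) and newborn neuron genes (-0.51) were lower by camera, with adjusted p of 0.000315, 0.0095 and 0.0409, although 0 of their members passed. These became adjusted p = 0.988 with an estimated correlation for the first 2 and 0.456 for newborn neurons. With the brightness trend removed the camera adjusted p was 0.335 for the first 2 and 0.298 for newborn neurons. Adjusted over the list alone, 0 ribosomal, 0 respiratory chain and 2 newborn neuron genes were lower. Olfactory receptor probes had a median difference of 0.13. With the position trend removed from each array 0 probes passed, and 0 passed when only the fetal arrays entered the fit. Other settings gave more, with 361 after scaling, 306 after quantile normalization, 696 by robust regression and 182 without fetal occipital replicate 5.

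In the adult 0 probes differed between regions by limma, with 611 at an unadjusted p under 0.05 and 0 by robust regression. The smallest p belonged to AY036118 (2.51 ± 0.57), Tnfsf10 (1.62 ± 0.42) and Dnah7b (1.62 ± 0.44) among higher and to Gnb4 (-1.47 ± 0.45), Etv2 (-1.24 ± 0.39) and Apba1 (-1.74 ± 0.56) among lower occipital ratios, with a limma adjusted p of 0.998 for each. Camera called ribosomal (median difference -0.21, adjusted p 0.00162) and respiratory chain genes (-0.15, adjusted p 0.0193) lower in occipital cortex, with adjusted p = 0.602 and 0.617 with an estimated correlation, 0 members passing and 0 adjusted over the list alone. With the brightness trend removed the camera adjusted p was 0.13 for ribosomal and 0.209 for respiratory chain genes. Pro-apoptotic, survival, immediate early and dopamine genes had 0 members passing in either region comparison. Adjusted over the list alone, 2 pro-apoptotic genes, 1 survival gene and 1 immediate early gene were lower and 1 survival gene higher in fetal occipital cortex, and 0 in the adult.

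The age comparison asked where the adult ratio differed from the fetal one. Mbp, the myelin basic protein gene, differed by 2.91 ± 0.37. Its mean was -1.40 in the fetal arrays, below 0 on 10 of 10, and 1.51 in the adult arrays, above 0 on 10 of 10. The microtubule protein Map1a (2.59 ± 0.46), the neuronal surface antigen Thy1 (2.46 ± 0.37), Cyp4f14 (2.44 ± 0.51) and the palmitoyltransferase Zdhhc1 (2.41 ± 0.48) were also higher in adults. The mitotic kinesin Kif23 (-1.98 ± 0.34), 4930402K13Rik (-1.88 ± 0.35), the proton pump subunit Atp6v1c2 (-1.84 ± 0.31), the germline gene Tex19.1 (-1.80 ± 0.39) and the urocortin 2 gene Ucn2 (-1.80 ± 0.34) were lower, Kif23 averaging 0.25 in fetal and -1.72 in adult arrays. Limma adjusted p ran from 0.000128 to 0.00553 for these 10 genes over 20 arrays. Second probes gave 0.18 ± 0.29 for Map1a and 0.25 ± 0.43 for Kif23, neither of which passed. In total 3525 probes passed, 1609 higher and 1916 lower in the adult.

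**Figure D4:**
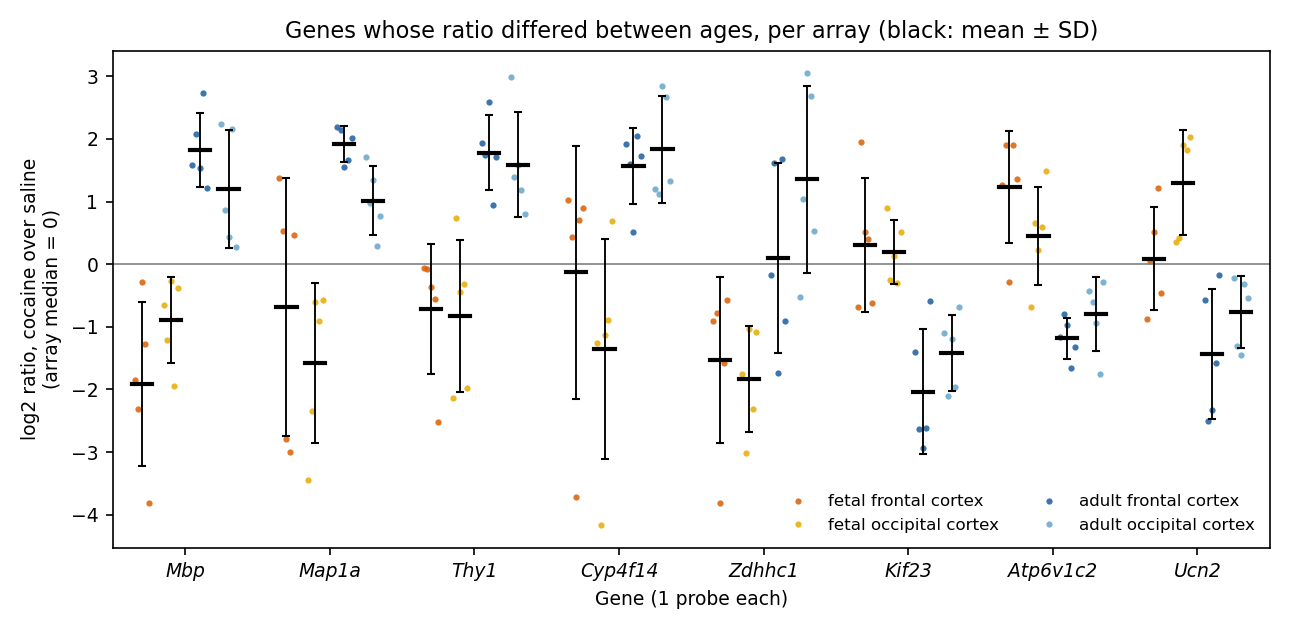
Log2 ratio of cocaine over saline (vertical axis, array median at 0) of 8 genes whose ratio differed between ages, on each of the 20 arrays, with points for arrays, colours for the 4 groups and black bars for mean ± SD of 5 arrays. Mbp lies below 0 on all 10 fetal arrays and above 0 on all 10 adult arrays, with means of -1.40 and 1.51.

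Genes of the mature brain were higher in the adult ratios by camera at the preset correlation. Of 15 astrocyte genes 9 were higher, 0 lower and 6 did not pass (10 and 0 adjusted over the list alone), with the gap junction gene Gja1 at 1.69 ± 0.33, Clu at 1.45 ± 0.31 and the glutamate transporter Slc1a3 at 1.55 ± 0.34. Of 30 synaptic genes 10 were higher, 1 lower and 19 did not pass (13 and 1 adjusted over the list alone), with Syt1 at 1.57 ± 0.31 and Vamp2 at 1.99 ± 0.42. Respiratory chain genes had 17 higher, 0 lower and 40 not passing (23 and 0 adjusted over the list alone), with Cox6b1 at 1.35 ± 0.32. In the GABA system 5 of 17 were higher, 1 lower and 11 did not pass (6 and 1 adjusted over the list alone), with the synthesis enzymes Gad1 at 1.64 ± 0.28 and Gad2 at 1.24 ± 0.27 and the degrading enzyme Abat at -1.20 ± 0.34. Interneuron markers, which share Gad1 and Gad2 with that list, had 5 of 20 higher, 0 lower and 15 not passing (10 and 0 adjusted over the list alone), with somatostatin, Sst, at 1.68 ± 0.31. Myelin genes had 6 higher, 0 lower and 14 not passing (8 and 0 adjusted over the list alone), with Trf at 1.87 ± 0.44 and Mal at 1.47 ± 0.42. Camera adjusted p for these 6 lists ran from 7.44e-07 to 0.0236, with adjusted p = 0.106 with an estimated correlation for astrocytes, 0.235 for synaptic, 0.361 for respiratory chain, 0.267 for GABA and myelin and 0.279 for interneuron genes. With the brightness trend removed the camera adjusted p stayed under the threshold for respiratory chain (0.00145) and synaptic genes (0.0125), whose medians went from 0.49 to 0.45 and from 0.76 to 0.54. It was 0.0654 for astrocyte (median 0.85 to 0.61), 0.572 for interneuron (0.44 to 0.18), 0.755 for GABA (0.54 to 0.07) and 0.796 for myelin genes (0.39 to 0.22). The brightness score itself was higher in adult arrays, by a median of 0.57 over all probes. The rise was 1.21 for astrocyte, 1.25 for myelin, 0.99 for GABA, 0.75 for interneuron, 0.66 for synaptic and 0.21 for respiratory chain probes. The score also rose in lists with little age difference in ratio. It rose by 1.11 for hippocampal markers (ratio difference 0.02), 1.08 for serotonin, noradrenaline and acetylcholine genes (0.04) and 1.01 for death receptor genes (0.03). Other lists not called by camera had a like rise and a larger ratio difference. The rise was 1.00 for striatal markers (0.55), 1.03 for immediate early genes (0.27) and 0.97 for glutamate receptors (0.23).

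Camera also called targets of p53, hypoxia and ribosomal genes. Of 15 p53 targets 3 were higher, 0 lower and 12 did not pass, the same adjusted over the list alone, namely Ccng1 (1.37 ± 0.32), Mdm2 (1.13 ± 0.31) and Perp (0.79 ± 0.28). Hypoxia response genes had 5 of 24 higher, 1 lower and 18 not passing, the same adjusted over the list alone, with the glycolytic enzymes Pfkp at 1.41 ± 0.33 and Hk2 at -1.06 ± 0.29. Ribosomal genes had 5 of 52 higher, 2 lower and 45 not passing (4 and 2 adjusted over the list alone), with Rpl13 at 1.53 ± 0.33 and Rps18 at -1.06 ± 0.30. Camera adjusted p was 0.0236, 0.0476 and 0.0162, with adjusted p = 0.267, 0.304 and 0.693 with an estimated correlation. With the brightness trend removed the camera adjusted p was 0.626, 0.796 and 0.0654 in the same order, while the medians went from 0.51 to 0.44, from 0.42 to 0.20 and from 0.33 to 0.45. Pro-apoptotic genes had 4 higher, 4 lower and 23 not passing (6 and 6 adjusted over the list alone), with Cycs at 1.65 ± 0.36 and Casp1 at -1.16 ± 0.28. Dopamine genes had 3 higher, 0 lower and 14 not passing (4 and 0 adjusted over the list alone), with Maoa at 1.38 ± 0.32 and Ppp1r1b at 1.57 ± 0.45. Immediate early genes had 4 higher, 2 lower and 20 not passing, also 4 and 2 adjusted over the list alone, with Dusp6 at 1.43 ± 0.26. Survival genes had 2 higher, 0 lower and 19 not passing (1 and 0 adjusted over the list alone). Over all probes 15.6% passed between ages. The count of probes was 1873 with arrays scaled to equal spread, 6886 by robust regression and 2226 without adult frontal replicate 2. With both trends removed Ccng1 stood at -0.11 and Mdm2 at -0.13, which did not pass, and Btg2, which did not pass before at 0.64 ± 0.28, passed at -0.83 with a limma adjusted p of 0.0164.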

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

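The test of a difference between the dyes that depends on brightness was chosen after its result was seen, and the brightness and position adjustments were chosen after the data had been seen, as were the count of calls kept in the 4 groups and the look at the arrays of the highest split.

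Among 188 groups of values tested for a single array far from the others 13 stood out, where chance alone picks about 1 in 20 groups. In fetal frontal cortex replicate 1 stood apart for Adpgk at 5.72 and for the astrocyte median at -0.35, replicate 4 for Elf3 at -5.41, and replicate 2 for the newborn neuron median at 1.36. In fetal occipital cortex replicate 1 stood apart for Mtcl1 at 2.54 and replicate 1b for the interneuron median at 0.22. Over the 10 fetal arrays Ten1 stood apart at 5.31 on frontal replicate 1 and Olfr1301 at -5.57 on occipital replicate 1b. In adult frontal cortex replicate 5 stood apart for the p53 target median at -0.33. In adult occipital cortex replicate 1 stood apart for the respiratory chain median at 1.87 and the GABA median at 0.73, replicate 2 for the interneuron median at 0.73, and replicate 3 for its 13 marker values.

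The response differed between the fetal regions for 5 probes, 4 of them named: Dapp1 at -2.69, Gp1bb at -2.65, Clec3b at -2.37 and Pdlim4 at -2.17. Gene lists differed too by camera at the preset correlation, with 0 members passing in either region comparison. Between the fetal regions the median difference was -0.55 for ribosomal, -0.35 for respiratory chain and -0.51 for newborn neuron genes, and between the adult regions -0.21 for ribosomal and -0.15 for respiratory chain genes. With an estimated correlation none of these was called: adjusted p = 0.988, 0.988 and 0.456 in the fetus and 0.602 and 0.617 in the adult, in the same order. Between the ages 3525 probes differed, with Mbp at 2.91, Map1a at 2.59, Thy1 at 2.46, Cyp4f14 at 2.44, Zdhhc1 at 2.41, Kif23 at -1.98, 4930402K13Rik at -1.88, Atp6v1c2 at -1.84, Tex19.1 at -1.80 and Ucn2 at -1.80. The age differences of list medians were 0.85 for astrocytes, 0.76 for synaptic, 0.54 for GABA, 0.51 for p53 target, 0.49 for respiratory chain, 0.44 for interneuron, 0.42 for hypoxia, 0.39 for myelin and 0.33 for ribosomal genes. These 9 lists also lost their call with an estimated correlation, and 2 of the 9, respiratory chain and synaptic genes, kept it with the brightness trend removed. In that setting the medians of the 9 lists lay between 0.07 for GABA and 0.61 for astrocyte genes, and that of ribosomal genes was 0.45 against 0.33 before.

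The first pattern is the large number of probes past the threshold against 0 in every group. A difference between the dyes that depends on brightness had the values it needs: the median Spearman correlation of log ratio with brightness score over the 20 arrays was 0.586, and the olfactory and vomeronasal receptor probes had a median of -0.37. The score was built from the same ratios and is no independent measure of brightness. With the score's trend removed the count over the 4 groups was 20811 against 37481, or 55.5%. Of the 37481 calls 15295 (40.8%) still passed in the same direction, 38 passed in the opposite one, and 5478 calls were new. The percentage of the counts exceeds the bound of 50% set beforehand against brightness as the whole cause, but the bound was wrong, because the score follows bright spots with a correlation of only 0.0861 in simulated data and cannot remove their trend. An effect of cocaine on these genes, a fixed difference of the dyes for single probes and the rest of the brightness trend therefore cannot be told apart without a dye swap.

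Turning the signs of single arrays tests whether the arrays of a group share their ratios. For the single groups the 16 sign patterns of 5 arrays are too few for a share under 0.05: over the 22473 probes with a value on every array the real pattern gave 8361 probes in fetal frontal, 5586 in fetal occipital, 12664 in adult frontal and 10883 in adult occipital cortex, and the highest other pattern 1538, 1271, 4115 and 3. For the mean of both regions chance can be excluded at both ages, since only the real pattern, 1 of 100 drawn, gave as many. The counts were 11103 with a highest other of 8037 in the fetus, and 14970 with a highest other of 13098 in the adult. These counts do not say whether dye or exposure is shared.

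The second pattern is the higher adult ratio of mature brain genes, such as Mbp, Thy1, Gja1 and Syt1. Chance can be excluded for the count of all probes that differed between ages in either direction. Of 100 splits of the 20 arrays only 1, the real one, gave 3525 probes, and the highest other gave 0. The splits did not count the mature brain lists by themselves. The change of transcript abundance with age may act through the brightness trend: the age difference of the ratio correlated across probes with that of the score at a Spearman coefficient of 0.112, between the bounds of 0.05 and 0.2 set beforehand, so this test decides neither way. After adjustment by brightness scores of each age 48.5% of the calls, 1708 of 3525, still passed in the same direction and 8 passed in the opposite one, just under the bound of 50% set against the score as the whole cause. The count after adjustment was 5965, where the score as the whole cause predicts 0. With the position trend removed instead the count was 3411. For single genes such as Map1a, Cyp4f14 and Zdhhc1 position on the array stays open. Also open are abundance acting through brightness, which the score does not fully remove, and a lasting or age-dependent effect of cocaine. Slides of the 2 ages handled apart are a further open explanation, and these cannot be told apart here.

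The third pattern is the set of 5 probes that differed between the fetal regions. Position on the array explained from 2.72% of an array's variance to 45.9% in fetal occipital replicate 1b, and after its removal 0 of the 5 still passed, as position as the source predicts. The differences shrank from between -2.17 and -2.92 (SE 0.40 to 0.55) to between -1.34 and -2.07 (SE 0.37 to 0.46), with adjusted p from 0.067 to 0.163. For Clec3b, Pdlim4 and Gp1bb the calls ended because the differences shrank while the SE changed less, to unadjusted p of 0.000583, 0.00226 and 0.00114. For Dapp1 the SE shrank nearly as much as the difference, and the unadjusted p rose from 7.11e-06 to 1.35e-05. For the probe without a gene name the unadjusted p went from 9.56e-06 to 5.94e-06, so that call ended through the adjustment over all probes. By probe number and the inferred row length, all 5 probes lay towards the same end of the array rows. The named fetal occipital falls other than Col1a2 lay there too. This placement goes with position as the source, which stays open for the probe without a gene name. In the splits of the 10 fetal arrays 3 of 100 gave as many as the real 7 among probes with every value. That share lies under the bound of 0.05 set beforehand. Chance stays open all the same, since leaving out 1 array brought the main count of 5 to as low as 0. The highest other split gave 239, several times the real count, which points to a structure of the samples. That split is the real one with fetal occipital replicate 5 and fetal frontal replicate 3 exchanged. It parts the fetal arrays by their Spearman correlation of log ratio with brightness score. These were 0.516 to 0.657 on the side of fetal occipital replicate 5 and 0.0903 to 0.479 on the other. The cause of the split was not tested. A difference in response between the regions stays open as well. In the adult the real count was 0, which all 100 splits reach whatever the samples hold (highest other 0), so the splits decide nothing there.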

How the results depend on the processing

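The brightness and position settings and the joint removal of fetal occipital replicates 1 and 1b were chosen after seeing the data. Of 388 results for named genes, 358 of them past the threshold, 12 turned in sign under some setting and 85 called ones lost the threshold under some planned setting; of 46 list results 0 turned in sign, but all 46 lost their call with the correlation estimated from the data, 29 with the brightness trend removed, 23 with both trends removed and 6 with fry. With the brightness trend removed the lists that kept their call were 2 of 5 in fetal frontal, 0 of 1 in fetal occipital, 5 of 7 in adult frontal and 3 of 7 in adult occipital cortex, 0 of 5 in the fetal and 5 of 7 in the adult mean, 0 of 3 and 0 of 2 between fetal and adult regions, and 2 of 9 between ages. The cause was not tested except where stated. With fetal frontal replicate 1 turned in sign 9 probes passed in fetal frontal cortex, 6826 in the fetal mean and 0 in the fetal region difference. Sox4 then stood at -0.23 in fetal frontal cortex, and 65 named gene results lost the threshold. As deposited, that array correlated with its group from 0.36 to 0.57, so this setting turns it against its group. With the brightness trend removed the counts were 3424 in fetal frontal, 8294 in adult frontal, 5334 in adult occipital cortex, 6878 in the fetal mean and 5965 between ages. In fetal frontal cortex 1 of the 2 Sox11 probes stood at -0.15, Cnp (adult occipital) at -0.042 and Btg2 (between ages) at -0.49. With the position trend removed the counts were 3089 in fetal occipital cortex and 0 for the fetal region difference. Of the 388 named gene results 25 lost the threshold in that setting and 0 turned in sign. With both removed they were 4905, 1802 and 6862 in fetal frontal, fetal occipital and adult occipital cortex, 6902 in the fetal mean, 0 for the fetal region difference and 6331 between ages. In that setting Birc5 stood at -0.026, Drd3 at -0.17, Slc18a2 at -0.045 and the same Sox11 probe at -0.23 in fetal frontal cortex. In fetal occipital cortex Slc18a2 stood at -0.020 and Xiap at 0.26, and in the fetal mean Sox11 at -0.010. Between ages Btg2 stood at -0.83 (limma adjusted p 0.0164, past the threshold in the opposite direction), Ccng1 at -0.11 and Mdm2 at -0.13. Without fetal occipital replicates 1 and 1b there were 3646 in that region and 0 for the fetal region difference. With only the arrays of the comparison, where fewer arrays estimate the spread, there were 1744 and 0. Between ages scaling gave 1873, robust regression, which did not converge for 253 probes, 6886, and a threshold of 0.1 gave 5588. The fetal region difference, main count 5 with 0 higher and 5 lower, gave 9 without centring (1 higher, 8 lower), 361 with scaling (105 and 256), 306 with quantile normalization (115 and 191), 8 with exact 0 as missing, 104 with array weights, 696 by robust regression and 157 at a threshold of 0.1. Whether the title numbers pair the samples is not known. Deviations of arrays with the same number correlated from -0.13 to 0.38, and arrays of unlike number were not compared. With that number as a replicate block (consensus correlation 0.0412) the fetal region count was 8, and no other count moved by over 1.5 times. Without centring, array medians lay between -0.26 and 0.32.

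Leaving out 1 array at a time gave from 5243 (without replicate 2) to 8686 in fetal frontal, from 3109 (without replicate 5, and 3477 without replicate 1b) to 5938 in fetal occipital, from 10789 to 12914 in adult frontal and from 8575 to 11195 in adult occipital cortex, from 9583 to 11368 in the fetal and from 14295 to 15152 in the adult mean. Between ages it gave from 2226 without adult frontal replicate 2 to 4267, with 2309 without fetal frontal replicate 3 and 2339 without adult occipital replicate 2. The fetal region count ran from 0 to 182: 182 without fetal occipital replicate 5, 23 without its replicate 3, 2 without its replicate 4, 14 and 12 without fetal frontal replicates 3 and 4, 6 without adult frontal replicate 3, and 0 without any 1 of the other 14 arrays. The adult region count was 0 in every setting run. Counts not given here stayed within 1.5 times the main count. Signal over background was not analysed here, so no value can be weighed by its depth.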

Other observations

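Other gene lists moved less or in both directions. Blood cell genes had 9 lower, 4 higher and 2 not passing of 15 in the adult mean, with a median of -0.78, and genes of the meninges 10 lower, 5 higher and 3 not passing of 18, with a median of -0.59; in the fetal mean these were 4 lower and 1 higher, and 6 lower and 3 higher. Cell cycle genes had 17 lower and 11 higher of 39 in the adult mean and 12 lower and 9 higher in the fetal mean. Interferon response genes had 10 lower and 6 higher of 24 in the adult and 9 lower and 3 higher in the fetal mean. Glucocorticoid response genes had 8 higher and 1 lower of 17 in the adult and 9 higher and 3 lower in the fetal mean. Axon guidance genes split into 16 higher and 7 lower of 37 in the fetal and 14 higher and 13 lower in the adult mean. None of these lists passed camera in either mean. Over all probes 66.4% passed in the adult and 49.2% in the fetal mean.

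Markers of several other cell types had members in both directions. Interneuron markers had 4 higher and 4 lower of 20 in the fetal and 10 higher and 2 lower in the adult mean. Radial glia genes had 6 higher and 3 lower of 20 in the fetal mean, cortical projection neuron genes 4 higher and 4 lower of 20, and Cajal-Retzius and subplate genes 6 higher and 3 lower of 12. Microglia genes had 8 higher and 5 lower of 16 and endothelial genes 9 higher and 6 lower of 21 in the adult mean. Striatal markers had 7 higher and 3 lower of 17, hippocampal markers 3 higher and 4 lower of 14, and thalamic markers 2 higher and 6 lower of 14 in the adult mean. Olfactory receptor probes had a median of -0.29 in the fetal and -0.53 in the adult mean.

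A hypothesis is that part of the shared ratios is a lasting effect of cocaine common to both ages. The fetal and adult mean ratios correlated across probes at 0.75, and at 0.37 after the brightness adjustment, which was chosen after the data had been seen. This may reflect a lasting effect, but a fixed difference between the dyes for single probes gives the same correlation, and no dye swap is labelled to part them.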
